A study of Mus musculus with 4 samples.

How the data were processed

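Total RNA of CCE mouse embryonic stem cells was made into rRNA-depleted libraries (Ribo-Zero) and sequenced on an Illumina HiSeq as 100-bp read pairs, per the labels' protocols. Ribosomal RNA depletion keeps transcripts without poly(A) tails, such as histone and small nucleolar RNAs, and whether the libraries kept strand is not given in the sources used here. The values analysed are FPKM (fragments scaled by transcript length and by the library's mapped fragments) that the authors computed and deposited, 1 table per library with 1 value per locus. TopHat2 2.0.10, Bowtie2 2.1.0, Cufflinks 2.1.1 and the mouse build mm9 are named per the submitters' processing notes, which give neither roles nor order. The annotation, any filter and any normalization across libraries are not given in the sources used here. FPKM are divided by the library's own total and by transcript length, so they show shares of the RNA and not amounts per cell, and overlapping or antisense genes may share fragments.

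Each table held the same 26528 loci, of which 3339 had no gene name and 320 named several genes. FPKM of loci with the same symbol were summed, which gave 22774 symbols, 314 of them from several loci. Unnamed loci were left out of the main fit. They held 95.4% and 94.9% of the FPKM sum in the shEV libraries and 81.4% and 90.6% in the shPspc1 libraries, mostly at loci of up to 150 bases. There FPKM reach very high values. At loci of 102 bases the estimated worth of 1 fragment ran from 19073 FPKM (shPspc1 replicate 1) to 51154 FPKM (shEV replicate 2). These percentages are therefore not shares of the fragments. Since FPKM are divided by the library's own total, their sum is no measure of depth. No counts were given and the depth per library is unknown, so no counting interval is given for any value. Pearson correlations of log2(FPKM + 1) between libraries ran from 0.954 to 0.970 across genes, and no library was a copy of another. The highest was between groups, for shEV replicate 1 and shPspc1 replicate 1, while the pairs within a group stood at 0.959 (shEV) and 0.961 (shPspc1).

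The libraries were grouped by the labels into shEV (2) and shPspc1 (2). The main test was limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend) on log2(FPKM + 1), a pseudocount of 1, over the 11254 symbols whose mean FPKM over the 4 libraries was at least 1. It was two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05, and group was the only term. Gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 21 lists with at least 5 measured genes, with camera at an estimated correlation and fry beside it. Camera compares a list with the other genes, while fry asks whether the list's genes move on balance in one direction. A gene was called separated when both libraries of a group lay above both of the other. The test, the lists, the other settings to be tried and the rule for named genes were fixed before the data were examined.

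The rule named Pspc1, Nono, Sfpq, Neat1, Tet1, Tet2, Tet3, Pou5f1, Nanog and Sox2, the 8 largest log2 fold changes in each direction among genes past the threshold, and up to 3 members of each list past the threshold. Where fewer passed in a direction, places were filled with the largest fold changes among separated genes with an unadjusted p under 0.05, and where no member of a list passed, the member with the largest absolute test value was taken. Symbols of small RNAs were not eligible among the largest changes. Neither were symbols that start with LOC, or with Gm, AK or BC plus digits, or that end in Rik. Gm8994, at a log2 fold change of 1.76, was left out by this rule though Defb13, at 1.71, was named. List members named beyond the rule (Sp110, Usp17la, Zscan4a, Zscan4b, Zscan4c, Zscan4e, Dux, Pgk1, Aldoa, Gapdh, Chac1, Shmt2, Hspa5 and Xbp1) were chosen after their values were seen.

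Alternatives were another pseudocount (0.1), no filter and a filter at 5 FPKM, 3 rescalings, small RNAs left out, eBayes without a trend, the replicate number as a block, the highest row in place of the sum per symbol, and each library left out. Genes listed at 0 in a library and at 10 FPKM or more in another left out (20 genes), the same with the block, and unnamed loci included were added after seeing the data. The fit was tested on simulated data for shPspc1 against shEV with 11122 genes, where it called 23% of 100 genes changed 2-fold, 100% of 100 genes changed 4-fold and 12 unchanged genes. The simulated noise was normal with the fit's own moderated spreads, and the changed genes were drawn from the better expressed ones. These shares therefore do not carry over to the real genes, where Pspc1 was 6.96 times lower and did not pass. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9. Transcript lengths for matched random lists came from GENCODE vM21, by symbol only, since its build differs from mm9.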

Results

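RNA was measured in 4 libraries of CCE cells, a mouse embryonic stem cell line of strain 129/Sv grown in serum with leukemia inhibitory factor on gelatin. Cells that carried an empty shRNA vector (shEV, 2 libraries) were compared with cells that carried an shRNA against Pspc1 (shPspc1, 2 libraries). PSPC1 is an RNA-binding protein of paraspeckles, the nuclear bodies built on the long noncoding RNA Neat1. The series asks how RNA brings the DNA demethylase TET2 to chromatin, and how endogenous retroviruses are kept in check in pluripotent cells. The knockdown comparison shows which transcripts differ once Pspc1 is depleted. Retroviral repeats themselves were not analysed here, so the comparison rests on genes, including those that are known to be transcribed from MERVL repeats in cells resembling the 2-cell embryo. Named gene symbols at 1 FPKM or more numbered 11165 and 11351 in the shEV libraries and 11052 and 11135 in the shPspc1 libraries. The files give FPKM without counts, and low values shared recognisable steps in only 1 of the 6 pairs of libraries (shEV replicate 2 and shPspc1 replicate 2, 7.78% of 1838 low loci in 1 window of 0.02 log2), so the depth is unknown. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

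Pspc1 itself, listed as locus XLOC_007364 on chromosome 14 from 57341285 to 57397153 of mm9, stood at 52.3 and 29.0 FPKM in the shEV libraries and at 8.42 and 3.26 FPKM in the shPspc1 libraries. The mean was 40.6 ± 16.4 (SD, n = 2) against 5.84 ± 3.65 (SD, n = 2), 6.96 times lower in the knockdown. Its log2 fold change, on the log2(FPKM + 1) scale, which understates the change of low genes, was −2.66 ± 0.43 (SE), with a limma adjusted p = 0.406 over 11254 genes. Both knockdown libraries lay below both controls, but the gene did not pass the threshold over all genes in this fit. With the replicate number as a block it passed (limma adjusted p = 0.000244), though the labels do not say what the numbers mark. The adjusted p was 1.07e-06 without shPspc1 replicate 1 and 0.00565 without shPspc1 replicate 2, fits that leave a single knockdown library, and over all settings tried it ran from 1.07e-06 to 0.78.

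Genes of the 2-cell-like state were higher in the knockdown as a group. The list named 38 genes, of which 36 rows were found and 22 had a mean of at least 1 FPKM and were measured. That mean ran over all 4 libraries. Tdpoz3 and Gm428, at shEV means of 0.726 and 0.630 FPKM, therefore passed through the knockdown libraries. All 22 measured members had a higher mean in shPspc1 than in shEV, and in 16 of them both knockdown libraries lay above both controls. Tdpoz3, a BTB-domain gene of the early embryo, stood at 0.726 ± 0.145 FPKM in shEV and 4.20 ± 0.128 in shPspc1 (SD, n = 2 each), 5.78 times higher. Sp110, a nuclear body protein, stood at 2.50 ± 0.469 and 7.55 ± 2.84 FPKM, 3.02 times higher. Usp17la, a deubiquitinase gene, stood at 1.28 ± 0.10 and 4.10 ± 0.337 FPKM, 3.21 times higher. The 6 measured Zscan4 genes, which mark the 2-cell embryo and act at telomeres, were from 1.27 (Zscan4c) to 2.01 (Zscan4b) times higher. Zscan4a, at 13.01 ± 2.55 and 21.3 ± 6.81 FPKM, and Zscan4e, at 6.90 ± 1.49 and 9.93 ± 2.00 FPKM, had separated libraries and the other 4 overlapping ones, while the summed FPKM of all 6 stood at 65.9 and 76.8 in shEV and at 127 and 77.4 in shPspc1. Dux, the transcription factor that activates many genes of this state, stood at 1.39 ± 0.728 and 1.85 ± 0.289 FPKM, also with overlapping libraries.

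The median log2 fold change of the 2-cell-like list was 0.95, with 1.24 between the libraries numbered 1 and 0.64 between those numbered 2. In limma's camera test with a preset correlation of 0.01 the list passed the threshold (adjusted p = 2.12e-21 over 21 lists). With an estimated correlation the p was 0.0691 and the adjusted p = 0.689, so that call was lost, and limma's fry gave an adjusted p = 0.482 for a shift in one direction. The number of members past the threshold was 13 adjusted over the list alone, each of them higher, and 0 over all genes tested. These counts take near-identical copies as separate members. Summed by family, with a gene without a listed copy as its own family, the 22 members made 11 families, 9 of them separated. The list's estimated correlation was 0.38, far above the preset 0.01. Reads of the Zscan4, Tdpoz and Usp17l genes, and of Gm5662, Gm8300 and BB287469, can be shared between near-identical copies, so values of single members are uncertain.

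**Figure D1:**
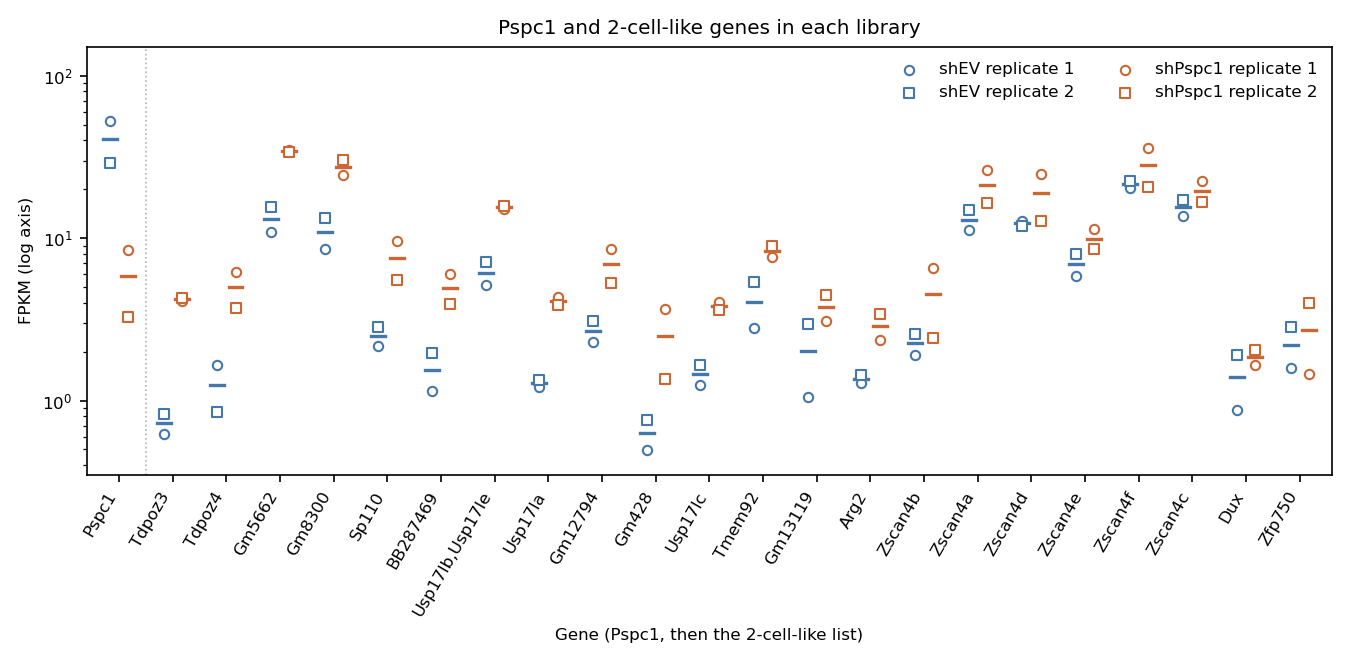
FPKM on a log axis for Pspc1 and the 22 measured 2-cell-like genes, ordered by fold change, with 1 point per library (blue shEV, orange shPspc1, circles replicate 1, squares replicate 2) and bars at the group means. Pspc1 stands at 52.3 and 29.0 FPKM in shEV and at 8.42 and 3.26 FPKM in shPspc1, while the orange bar lies above the blue bar in all 22 listed genes.

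Genes of glycolysis and of the response to hypoxia were lower in the knockdown as a group. All 24 measured members had a lower mean in shPspc1, and in 17 both knockdown libraries lay below both controls. Egln3, a prolyl hydroxylase that hypoxia induces, stood at 18.9 ± 17.2 FPKM in shEV and 2.70 ± 0.787 in shPspc1 (SD, n = 2 each), 6.98 times lower. Bnip3, a mitophagy receptor that hypoxia also induces, stood at 121 ± 82.5 and 34.4 ± 19.6 FPKM, 3.52 times lower. Both folds rest largely on shEV replicate 2: Egln3 stood at 6.74 and 31.0 FPKM and Bnip3 at 62.9 and 180 FPKM in shEV replicates 1 and 2, and their log2 fold changes were −2.10 and −1.72 with it and −1.08 and −0.97 without it. The log2 fold change of Bnip3 also shrank without shPspc1 replicate 2, to −1.12, and between the libraries numbered 1 it was −0.37. Among the glycolytic enzymes Pgk1 stood at 740 ± 259 and 365 ± 150 FPKM and Aldoa at 1175 ± 159 and 677 ± 164 FPKM, while Gapdh, at 3482 ± 752 and 3383 ± 1114 FPKM, was 1.03 times lower with overlapping libraries. The list's median log2 fold change was −0.73, with −0.30 between the libraries numbered 1 and −1.29 between those numbered 2. It passed the camera threshold with the preset correlation (adjusted p = 9.22e-14). With an estimated correlation the p was 0.125 and the adjusted p = 0.689, and fry gave an adjusted p = 0.5. The number of members past the threshold was 0 adjusted over the list alone and 0 over all genes, and 9 had an unadjusted limma p under 0.05, all lower. The control libraries differed from each other for these genes, by a median of 0.43 on the log2 scale (shEV replicate 2 minus replicate 1), as did the knockdown libraries, by −0.50 (shPspc1 replicate 2 minus replicate 1), and without shEV replicate 2 the list's median was −0.49.

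**Figure D2:**
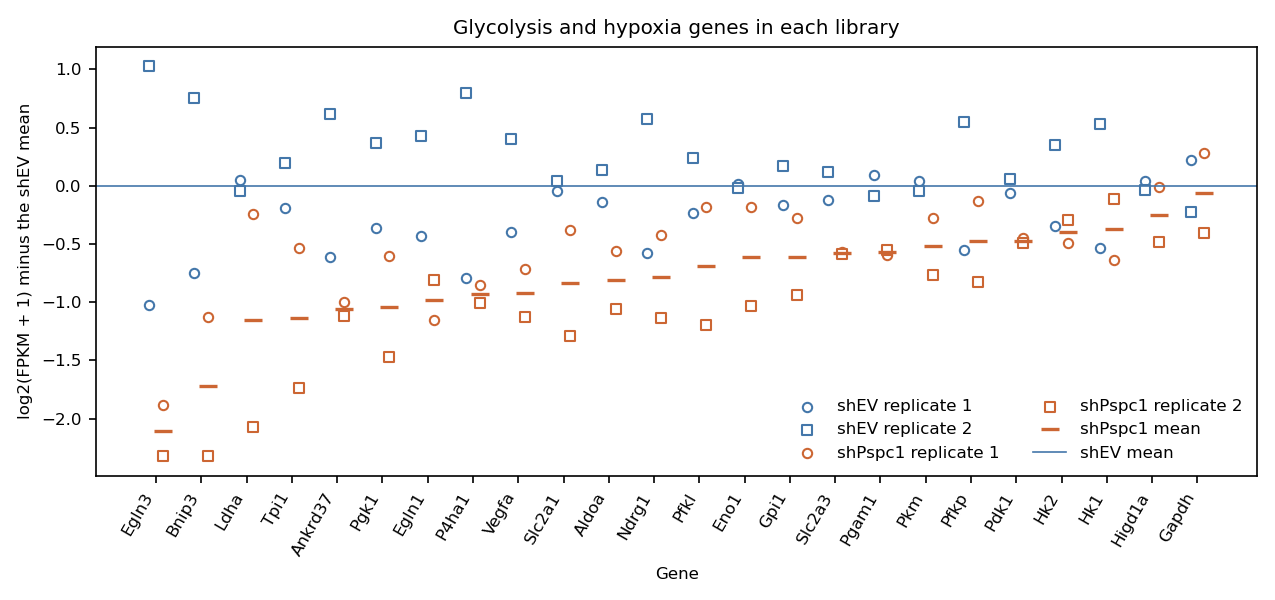
Log2(FPKM + 1) of 24 glycolysis and hypoxia genes in each library, relative to the shEV mean of the gene (line at 0), with orange dashes at the shPspc1 mean. All 24 dashes lie below 0, and the blue squares of shEV replicate 2 lie above the blue circles of replicate 1 by a median of 0.43.

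Genes of the integrated stress and unfolded protein response went both ways. Of the list's 25 measured members 17 had a lower mean in shPspc1 and 8 a higher one, with 12 separated lower and 4 separated higher. Phgdh, the first enzyme of serine synthesis, stood at 97.4 ± 20.2 FPKM in shEV and 38.4 ± 21.6 in shPspc1 (SD, n = 2 each), 2.54 times lower, and without shPspc1 replicate 2 its log2 fold change went from −1.42 to −0.84. Chac1, which degrades glutathione, stood at 11.8 and 16.0 FPKM in the shEV libraries and at 8.25 and 2.59 in the shPspc1 libraries, and the mitochondrial serine enzyme Shmt2 at 156 ± 3.72 and 91.7 ± 19.2 FPKM. The endoplasmic reticulum chaperone Hspa5 stood higher, at 217 ± 26.3 and 284 ± 6.73 FPKM, as did the unfolded protein response factor Xbp1, at 36.1 ± 2.14 and 46.1 ± 5.38 FPKM. The list's median log2 fold change was −0.18 (−0.11 between the libraries numbered 1, −0.25 between those numbered 2), and it passed the camera threshold in the lower direction with the preset correlation (adjusted p = 0.0399). With an estimated correlation the p was 0.215 and the adjusted p = 0.689, fry gave an adjusted p = 0.5, and no member passed adjusted over the list alone. The call also ended without shEV replicate 2 (adjusted p = 0.0788) and without shPspc1 replicate 2 (adjusted p = 0.464), and under 3 other settings, with adjusted p-values from 0.000216 to 0.464 over the settings tried with the preset correlation.

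The remaining 18 lists of at least 5 measured genes did not pass, none of their members passed the threshold over all genes tested, and 0 passed adjusted over the list alone. Among the 21 paraspeckle genes (median log2 fold change −0.11, camera adjusted p = 0.375) Neat1 stood at 15.4 ± 9.17 FPKM in shEV and 5.33 ± 3.58 in shPspc1 (SD, n = 2 each), while the PSPC1 partners Nono, at 202 ± 19.06 and 230 ± 19.9 FPKM, and Sfpq, at 203 ± 48.1 and 191 ± 24.4 FPKM, had overlapping libraries. Enzymes of DNA methylation and demethylation had a median of −0.07 over 22 genes (adjusted p = 0.928). Tet1 stood at 50.4 ± 27.2 and 45.0 ± 22.1 FPKM, Tet2 at 20.7 ± 9.26 and 18.2 ± 8.63 and Tet3 at 1.51 ± 0.30 and 1.29 ± 0.381, all with overlapping libraries, and Gadd45a, a stress-induced DNA repair factor, stood at 36.0 ± 6.01 and 71.8 ± 27.4 FPKM. Naive pluripotency genes had a median of 0.08 over 30 genes (adjusted p = 0.484). The core factors Pou5f1, at 1354 ± 476 and 1373 ± 111 FPKM, Nanog, at 201 ± 11.8 and 212 ± 15.0, and Sox2, at 252 ± 14.6 and 213 ± 50.6, overlapped between the groups, and Tcl1, a coactivator of AKT, stood at 42.7 ± 1.18 and 21.5 ± 9.84 FPKM. The 25 formative and primed pluripotency genes had a median of 0.03 but a mean of −0.09, and camera's direction was down (adjusted p = 0.77). Lefty2, an inhibitor of NODAL, stood at 79.9 ± 48.9 and 21.9 ± 2.04 FPKM there. Neat1's log2 fold change was −0.17 between the libraries numbered 1 and −2.60 between those numbered 2, and it went from −1.38 to −0.78 without shEV replicate 2 and to −0.77 without shPspc1 replicate 2. Without shPspc1 replicate 2 that of Gadd45a went from 0.93 to 0.54 and that of Tcl1 from −1.03 to −0.57, and without shEV replicate 2 that of Lefty2 went from −1.68 to −1.02.

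Lists that mark other cell types were among those that did not pass, and only a part of each was measured. They named 27 primitive streak and mesoderm, 28 endoderm, 24 trophectoderm, 27 neural and 25 fibroblast and mesenchyme genes. Members below a mean of 1 FPKM went untested. The medians were −0.06 over 7 primitive streak and mesoderm genes (adjusted p = 0.89), 0.07 over 11 endoderm genes (adjusted p = 0.53), 0.25 over 10 trophectoderm genes (adjusted p = 0.354), −0.12 over 13 neural genes (adjusted p = 0.181) and 0.08 over 11 fibroblast and mesenchyme genes (adjusted p = 0.555). Members with the strongest test value were Sp5 (3.45 ± 2.56 and 1.62 ± 1.51 FPKM), Fst (1.76 ± 0.322 and 4.56 ± 2.65), Hopx (6.48 ± 1.56 and 12.1 ± 0.344), Map2 (1.71 ± 0.0091 and 0.897 ± 0.0019) and Mmp2 (6.61 ± 1.59 and 3.41 ± 0.518), each as shEV and shPspc1 (SD, n = 2). Without shPspc1 replicate 2 the log2 fold change of Fst went from 0.93 to 0.43 and that of Sp5 from −0.77 to −0.14. Of the Hox genes 4 were measured, too few to test, with a median of −0.05, and Hoxc13 stood at 1.47 ± 0.065 and 0.952 ± 0.378 FPKM.

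Genes that silence retroelements had a median log2 fold change of −0.0005 and a mean of 0.0006 over 29 members (camera adjusted p = 0.928). Among them the histone demethylase Kdm1a stood at 129 ± 18.2 FPKM in shEV and 95.8 ± 10.2 in shPspc1 (SD, n = 2 each). Interferon and viral sensing genes had a median of 0.06 over 15 members (adjusted p = 0.354), and Oas1a, an antiviral oligoadenylate synthetase, stood at 0.941 ± 0.204 and 2.88 ± 0.692 FPKM. The germline list had a median of 0.05 over 19 genes (adjusted p = 0.354), with Tex19.1 at 33.1 ± 6.88 and 68.5 ± 19.8 FPKM and Rpl10l at 97.8 ± 0.869 and 161 ± 5.14 FPKM. The p53 targets had a median of 0.07 over 24 genes (adjusted p = 0.354), with Ei24 at 61.5 ± 3.85 and 121 ± 51.1 FPKM. Without shPspc1 replicate 2 the log2 fold change of Ei24 went from 0.91 to 0.47. Camera's direction for the p53 targets was up without shPspc1 replicate 1 and down without shPspc1 replicate 2. The 36 replication-dependent histone genes, many of which lack poly(A) tails and are kept by rRNA depletion, had a median of 0.07 (adjusted p = 0.354), with Hist3h2a at 2.42 ± 0.57 and 4.66 ± 0.462 FPKM. Ribosomal protein genes had a median of 0.04 over 83 members (adjusted p = 0.354), but 1 library turned their direction: they passed upward without shEV replicate 1 (adjusted p = 1.34e-07) and downward without shEV replicate 2 (adjusted p = 0.0152). Medians were lower for cholesterol synthesis, at −0.06 over 23 genes (adjusted p = 0.354), with Dhcr7 at 24.1 ± 0.766 and 15.7 ± 4.91 FPKM. Imprinted genes had a median of −0.18 over 26 members (adjusted p = 0.137), with the growth inhibitor Cdkn1c at 30.4 ± 10.8 and 15.9 ± 7.60 FPKM. The log2 fold change of Cdkn1c went from −0.93 to −0.45 without shPspc1 replicate 2 and to −0.57 without shEV replicate 1. That of Dhcr7 went from −0.61 to −0.31 without shPspc1 replicate 2, and that of Kdm1a from −0.43 to −0.28 without shEV replicate 2. The DNA replication and cell cycle list had a median of −0.10 over 32 members (adjusted p = 0.17), with the helicase subunit Mcm7 at 218 ± 33.0 and 124 ± 17.4 FPKM.

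**Figure D3:**
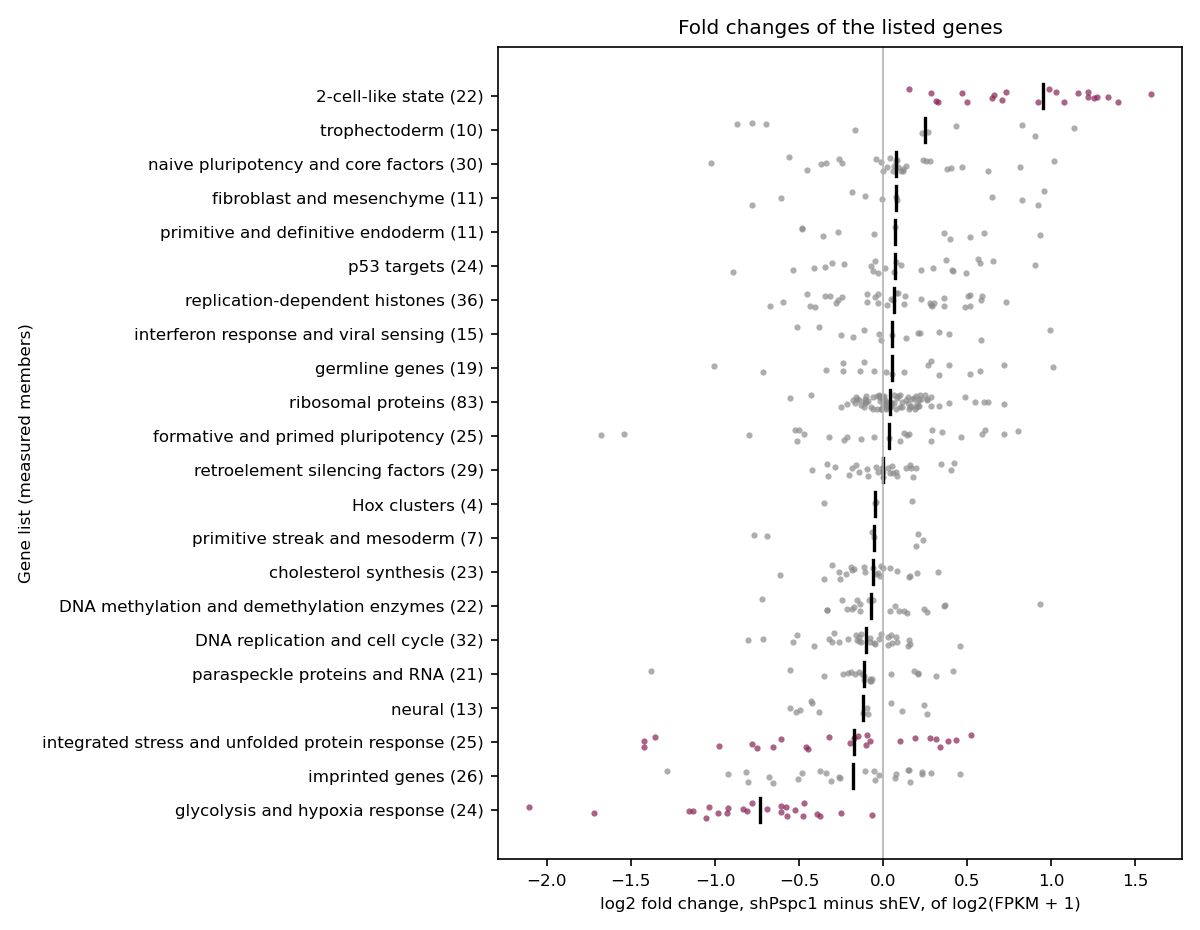
Log2 fold change (shPspc1 minus shEV, of log2(FPKM + 1)) of each measured gene, 1 row per list with the number of measured members, black bars at the medians and purple points for lists past the camera threshold with the preset correlation. The 2-cell-like list has its median at 0.95 and the glycolysis and hypoxia list at −0.73, and the other 20 medians lie between −0.18 and 0.25.

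Over single genes, 1 of 11254 passed an adjusted p of 0.05 in limma. This was Eef1a1, the main translation elongation factor, at 7531 and 6849 FPKM in the shEV libraries and listed at 0 in both shPspc1 libraries. It is a gene that every cell uses, so only the listing is given, and no fold. With the 20 genes listed at 0 in a library and at 10 FPKM or more in another left out, a choice made after seeing the data, 0 genes passed, and 578 had an unadjusted p under 0.05. Over all genes tested 543 had an unadjusted p under 0.05 (209 higher and 334 lower), 4.83% of them, no more than chance alone would give at 0.05. The balance between higher and lower genes was not stable, since it turned toward higher ones without shEV replicate 1. In 149 genes the log2 fold change was at least 1 in size and the libraries were separated (59 higher and 90 lower), a count that was 312 at a pseudocount of 0.1 and 174 to 431 with a library left out, while separation alone was met by 31.9% of genes, against 1 in 3 by chance.

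Of the genes named for the largest values in each direction, the others did not pass. Higher in both knockdown libraries were Gpx2, a glutathione peroxidase, at 2.45 ± 0.138 FPKM in shEV and 11.3 ± 0.528 in shPspc1 (SD, n = 2 each), Cox7b2, a cytochrome oxidase subunit isoform, at 11.5 ± 3.87 and 44.4 ± 18.2, and Serpinb9b, a serine protease inhibitor, at 0.98 ± 0.029 and 6.50 ± 2.79. The adjusted p was 0.406 for Gpx2 and Serpinb9b and 0.645 for Cox7b2. Spink10 stood at 0.424 ± 0.45 and 3.91 ± 0.853 FPKM, Htra1, a secreted protease, at 4.16 ± 0.683 and 16.9 ± 11.5, and the surface protein gene Ly6a at 0.202 ± 0.0227 and 3.74 ± 3.99. Defb13 was listed at 0 in both shEV libraries and stood at 3.94 and 1.17 FPKM in the shPspc1 libraries. Lower in both knockdown libraries were Ndufa4l2, which hypoxia induces, at 36.9 ± 40.9 and 1.86 ± 1.93 FPKM, the circadian repressor Bhlhe40 at 15.7 ± 14.8 and 2.58 ± 1.05, and Nxph4 at 4.87 ± 3.71 and 0.644 ± 0.188. Their adjusted p-values were 0.742, 0.848 and 0.742. Without shEV replicate 2 the log2 fold changes went from −3.28 to −1.83 for Ndufa4l2, from −1.90 to −0.84 for Bhlhe40 and from −1.68 to −0.98 for Nxph4, and without shPspc1 replicate 2 from 1.64 to 0.93 for Htra1 and from 1.67 to 0.68 for Ly6a. Of the 43 named genes 28 had a log2 fold change that shrank by over 1.5 times or turned sign when 1 library was left out.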

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

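The threshold was passed by 1 gene under each setting fixed beforehand that kept all 4 libraries without a block, by 13 and 7 without shEV replicates 1 and 2, by 74 and 24 without shPspc1 replicates 1 and 2, by 0 with genes listed at 0 left out, by 209 with the replicate block added to that, and by 9 with unnamed loci included. The labels share replicate numbers without saying what they mark, and with 2 pairs the deviations of same-numbered libraries correlated at 0.185 (Pearson) and 0.475 (Spearman) across genes (0.445 and 0.478 with genes listed at 0 left out), but the numbers were not taken as pairs. The replicate block moved the count to 37 genes (24 higher, 13 lower), with Pspc1 at −2.66 and an adjusted p of 0.000244, or 2.65e-06 with the zeros also left out, and ended no list's call at the preset correlation. At an estimated correlation the block raised camera's p from 0.0691 to 0.221 for the 2-cell-like list. For the glycolysis and hypoxia list it rose from 0.125 to 0.322. Among the genes that passed with the block were Gpx2, Cox7b2, Spink10, Serpinb9b, Defb13, Phgdh, Lefty2 and, of the 2-cell-like list, Tdpoz3, Tdpoz4, Gm5662, Gm8300, Usp17la and Usp17lb,Usp17le. With the block and the zeros left out imprinted genes also passed camera at the preset correlation (adjusted p 0.0339), but not at an estimated correlation (0.925). Among the single genes that passed limma in that fit were Ndufa4l2, Bhlhe40 and Nxph4 (adjusted p 0.00513, 0.0136 and 0.00513). Genes of at least 2-fold with separated libraries numbered 312 at a pseudocount of 0.1, 97 at 5 FPKM, 323 with unnamed loci and 174 to 431 without a library, where a group of 1 separates more easily. Lists past the threshold numbered 5 at 5 FPKM, where imprinted and cell cycle genes joined, 2 to 6 without a library, and 0 with an estimated correlation and with fry. The calls of the 2-cell-like list (0.95) and of the glycolysis and hypoxia list (−0.73) ended only under those latter tests (adjusted p 0.689 for both, and 0.482 and 0.5 with fry), and their medians ran from 0.76 to 1.14 and from −1.02 to −0.49 without a library. The stress list's call also ended without the filter (−0.16, adjusted p 0.277), with a median of ratios (−0.17, 0.0655), with unnamed loci (−0.18, 0.0852) and with fry (0.5), and ran from −0.26 to −0.15 without a library. Lists that did not pass crossed the threshold without single libraries: ribosomal protein genes up without shEV replicate 1 (adjusted p 1.34e-07, and 0.00583 under quantile normalization) but down without shEV replicate 2 (0.0152), germline genes up (0.00327) and cell cycle genes down (0.0348) also without shEV replicate 2, and p53 targets up (0.000245), neural genes down (0.0318) and imprinted genes down (0.00704) without shPspc1 replicate 1. The p53 direction was down, short of the threshold, without shPspc1 replicate 2 (0.0809). Without a library Pspc1 ran from −3.23 to −2.09, and signs turned for Sfpq (−0.31 to 0.17), Tet1 (−0.71 to 0.43), Tet2 (−0.66 to 0.29), Tet3 (−0.31 to 0.031) and Pou5f1 (−0.30 to 0.43). In such fits the lone library is assumed to vary like the other group. Of 699 values of single named genes under the alternatives 637 stayed on the same side in the same direction, 53 passed the threshold anew and 9 turned sign. The cause of these shifts was not tested, and the unknown depth leaves open how far low genes are limited by counting error.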

Other observations

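The tests of the glycolysis and hypoxia list and of the short unnamed loci were chosen only after the result was seen. Those of the 2-cell-like list were written before their results were, but after values of single genes had been seen.

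Outside the named genes, further transcripts were picked after their values were seen. Gm8994 stood at 10.2 ± 2.00 FPKM in shEV and 36.9 ± 4.96 in shPspc1 (SD, n = 2 each), Gm10696 at 1.06 ± 0.0907 and 4.91 ± 0.124, and Gm21319 at 1.84 ± 0.439 and 6.46 ± 0.371. None passed limma's threshold over all genes in the main fit (adjusted p 0.406, 0.406 and 0.645), while each passed with the replicate block (0.00951, 0.0113 and 0.02345). Predicted genes of this kind can share reads with near-identical copies. Among genes of NODAL signalling, picked in the same way, Lefty1 stood at 128 and 90.6 FPKM in the shEV libraries and at 74.9 and 17.4 in the shPspc1 libraries, while Nodal itself stood at 43.9 ± 2.59 and 46.1 ± 14.9 with overlapping ones. The trophectoderm list held the keratin genes Krt8, at 8.11 and 4.78 FPKM in the shEV and 8.69 and 25.2 in the shPspc1 libraries, and Krt18, at 5.28 and 4.00 and at 5.84 and 15.1, both high in shPspc1 replicate 2 alone, against Ascl2 at 3.00 ± 0.917 and 1.45 ± 0.416.

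The 2-cell-like list was higher in the knockdown libraries in all 22 measured members. Reads shared only between the measured members of a family would leave their sum alone, but the 5 families of several members had log2 fold changes from 0.47 (Zscan4) to 1.77 (Tdpoz) once their FPKM were summed. All 5 were separated, Zscan4 barely, and with the 6 genes that have no listed copy the median over families was 1.03. Copies that are not measured list members, such as the separate locus naming Gm5039 and Gm5662, were outside these sums. Reads shared with such copies were therefore not tested. Transcript length and expression level are argued against by the list's median exceeding 100.0% of 10000 random lists matched on both. A batch cannot be told apart from the knockdown: the lower median within a replicate number was 0.64, but each number holds both groups, so the bound set beforehand on that value was wrong and says nothing of groups handled apart. A candidate explanation that these tests leave open is a change with Pspc1 depletion in the share of cells in this state or in its genes' transcription, which the data cannot separate. Libraries of the same group also differed for this list, by a median of 0.31 in shEV and −0.26 in shPspc1 on the log2 scale (replicate 2 minus replicate 1). How much such variation adds to the difference between the groups was not tested. An off-target effect of the shRNA was not tested, since the labels name no further shRNA, and the call itself rests on the preset correlation.

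The glycolysis and hypoxia list was lower in all 24 members. Without the control library that mattered most the median shrank from −0.73 to −0.49 but stayed negative. Between the libraries numbered 1 it was −0.30, so a dependence of its size on single libraries is not excluded. Length and expression are argued against by the list lying below 100.0% of matched random lists. Culture conditions that vary between libraries, such as density or oxygen, remain a candidate explanation: the median difference between the control libraries was 0.582 of the size of the knockdown difference, with no knockdown between them, and the knockdown libraries also differed from each other, by a median of −0.50 on the log2 scale. An effect of Pspc1 depletion also stays open, and more cultures would be needed to tell it from such variation.

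Unnamed loci of up to 150 bases summed to 16.0 and 11.3, in units of 1e+06 FPKM, in the shEV libraries and to 3.03 and 6.48 in the shPspc1 libraries. A differing worth of 1 fragment between libraries was weighed as the source of this gap and cannot be told apart from a difference in these RNAs. Fragment numbers obtained by dividing by that worth had a ratio of 2.56 between the group means over 34 loci, and of 1.52 over 78 loci before lengths with uneven ratios of units were left out, a choice made after that first ratio was seen. Over the 34 loci the fragment numbers were 554 and 401 in the shEV libraries and 119 and 254 in the shPspc1 libraries. Such numbers are not scaled for depth, which is unknown, so neither ratio decides it, and what these loci hold was not analysed here.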
